A study of Plasmodium falciparum 3D7 with 2 samples.

How the data were processed

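ChIP-seq was carried out on blood-stage cultures of Plasmodium falciparum 3D7 with serum against the C-terminal part of PfGCN5, beside an input library, per the labels' protocols. The protocol in the labels also names a pre-immune serum; a library from it was not analysed here. The deposited data analysed were 1 peak list in the narrowPeak layout, with no replicate of the ChIP and no read counts for the input. The submitters' processing notes name Bowtie2 2.1.0 and MACS2 2.1.2. The role of each tool, the genome build, the treatment of duplicate reads and the control given to the peak caller are not given in the sources used here. Sequence names in the list end in v3, the naming of the third version of the 3D7 genome.

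Each deposited row holds the interval of a peak, its summit, a fold enrichment at the summit (a linear ratio), a −log10 p and a −log10 q, which are the authors' values from their peak caller. The deposited score equals 10 times the −log10 p, truncated to a whole number, and was not used further. These values served only to describe, rank and filter peaks within this list. The list kept peaks down to a −log10 p of 1.31, so 1065 of its 3396 peaks have a q above 0.05. No interval overlapped another. Peak positions are printed counted from 1, on the sequences of the list.

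Depth was read from the values themselves. The fold was taken as (pileup + 1) over (background + 1) and the p as the upper tail of a Poisson distribution with that background, the form used by MACS2. Solving both for each peak gave pileups within 0.01 of a whole number at 3384 of 3396 peaks. On 500 simulated peaks with known pileups, 96% were recovered within 0.01. The background was 119.6 fragments, within 0.1, at 2576 peaks, higher at 820 and lower at none. Pileups ran from 138 to 835 fragments. The 95% intervals of a fold are exact Poisson intervals of the pileup with the background taken as known. They cover counting error only, since sequenced fragments can be copies of 1 molecule.

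Genes came from a RefSeq gene table of assembly GCF_000002765.6 with 5615 genes on 14 chromosomes, 5282 of them protein-coding. The table gives locus tags and spans, with no strand, exons, product names or genome sequence, and its coordinates are not printed. The lengths of 63.6% of its protein-coding genes are multiples of 3, so many spans hold no untranslated regions. Since no source names the build of the peak list beyond its sequence names, the match was checked by shifting all summits in steps of 250 bp up to 5 kb each way. The share of summits in protein-coding genes was lowest within 250 bp of no shift on 14 of 14 chromosomes. Unshifted, it was 23.5% to 37.2%, against means of 57.6% to 65.7% at shifts of 3 kb or more. Gene names such as MSP1 were attached to locus tags from general knowledge and come neither from the deposited list nor from the gene table.

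Location was tested by random placement: each of the 3388 nuclear peaks was moved to a random position of its chromosome with its width and summit offset kept, in 10000 placements. The two-sided permutation p is the share of placements at least as far from their median as the observed value. Chromosome ends were taken as the last gene or peak end. Peaks per chromosome were compared with 10000 multinomial draws in proportion to length. Benjamini-Hochberg adjustment was applied over the chromosomes, over the distance classes and over the 14 gene lists, with a threshold of 0.05. A gene list was scored by its members with a summit in the span or within 1000 bp at each end, since without strand an upstream window could not be set. Shares have exact Clopper-Pearson 95% intervals. The difference in location between higher-fold and lower-fold peaks was tested by a permutation test with 100000 resamples. On 200 simulated lists without effect, 7% gave a p under 0.05 for the share in genes and 4% for a list of 30 genes. With 2% of summits moved out of genes 63.5% of lists were called and with 5% moved 100%. For lists of 30 genes the number of members with a summit was also raised to a set multiple of the random mean. At 1.5 times 100% had a p under 0.05 before adjustment, and at 1.2 times 1%. Since that number was set without sampling spread, these shares do not measure how often a real excess would be called.

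Before the data were examined, the tests of location class, subtelomeres, gene lists and chromosomes were fixed. So were the tRNA, rRNA and artemisinin response lists and the rule for named genes. The distance classes, the comparison by fold and the count of coding genes with a summit were not in that plan. Without strand and exons, the planned location classes were simplified. The planned window upstream of each gene became 1000 bp at each end. The other 11 lists were written by locus tag after the peak list had been seen but before any peak was set against a gene, because the planned lists used product names. The rule named the genes at the 20 peaks of highest fold, up to 4 members of each list with the highest peaks, the PfGCN5 gene and all artemisinin response genes, and up to 10 genes with 4 or more summits. Other genes are said to be named after their values were seen. Names for genes beside the top peaks were added after those peaks were known.

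Alternatives were peaks with a −log10 q of at least 5, peaks above the median fold, a circular shift of the peaks, the core without 100 kb at each chromosome end, windows of 500 and 2000 bp, other rules of overlap and subtelomeres of 50 and 200 kb. Added after seeing the data were a q at or under 0.05, gene spans alone, a placement that keeps each summit inside or outside genes, and leaving out a stretch of chromosome 10 with raised background. Exons, introns, 5′ flanks, orientation of neighbouring genes, GC content and mappability needed a genome or strand and were not run. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.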

Results

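PfGCN5 is the GCN5-family histone acetyltransferase of the malaria parasite Plasmodium falciparum, an enzyme that acetylates histone H3. Its positions on the genome were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the laboratory line 3D7. The cultures were unsynchronised blood-stage parasites enriched for trophozoites and schizonts, the growing and dividing stages inside the red blood cell. The series held 2 samples, 1 ChIP library made with serum against the C-terminal part of PfGCN5 and 1 input library, and the data analysed were 1 list of peaks. With 1 ChIP library there was no replicate check. Every p-value is a permutation p, from random placement of the peaks, from draws in proportion to chromosome length or from reassigning folds among the peaks. It is two-sided unless said otherwise, describes this list alone and is not a test over replicates. The number of reads per library was not analysed here. The values at the peaks corresponded to a median of 163 overlapping fragments at a summit, over a background of 119.6 fragments at 75.9% of the peaks. That value was also the lowest background in the list. At those peaks the fold therefore varied with the pileup alone, over the same background. Since the control given to the caller is not known, the folds cannot be read as enrichment over the local input.

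The list held 3396 peaks, of which 3388 lay on the 14 nuclear chromosomes and 8 on the genome of the apicoplast, the relict plastid of the parasite. Most of the peaks were shallow. The fold enrichment given by the authors' peak caller had a median of 1.34 (25th to 75th percentile, 1.27 to 1.43) and a highest value of 3.17. Only 34 peaks reached 2-fold and 468 peaks, 13.8% of the list, reached 1.5-fold. At the depth of this list the 95% Poisson interval around a fold had a median half-width of 0.209, and it covers counting error only. The interval included 1 at 83 peaks. That number does not tell how many peaks are real, since the p that limits the list rests on the same pileup and background. The list had been kept down to a −log10 p of 1.31, and 1065 peaks (31.4%) had a q above 0.05. Peaks were 241 to 2869 bp wide, with a median of 399 bp, and covered 7.15% of the nuclear span.

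The peak of highest fold had its summit within MSP1 (PF3D7_0930300). MSP1 is the gene of the major surface protein of the merozoite, the stage that invades red blood cells. The peak spanned chromosome 9 from 1199764 to 1202632 (Pf3D7 v3 sequence names) and had a fold of 3.17 (95% Poisson interval 2.86 to 3.50). The next in rank lay between genes, on chromosome 5 from 85543 to 86402 (3.07-fold), between RAP2 (PF3D7_0501600), a rhoptry protein gene 896 bp from the summit, and PF3D7_0501700, 687 bp from it. A peak on chromosome 12 from 917400 to 917835 (3.05-fold) lay between AP2-G (PF3D7_1222600), the regulator of sexual commitment, and GAP45 (PF3D7_1222700), a part of the invasion motor, with its summit 1161 bp from GAP45 and 3060 bp from AP2-G. The peak on chromosome 12 from 205432 to 206434 (2.90-fold) had its summit in the gene of the translation factor eIF5A (PF3D7_1204300). Of the 20 peaks of highest fold, these peaks in MSP1 and eIF5A were the only ones with a summit inside a protein-coding gene.

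Among the other peaks of these 20, that at 945615 to 945962 on chromosome 7 (2.84-fold) lay between PF3D7_0722100 and RALP1 (PF3D7_0722200), a rhoptry neck protein. On chromosome 9, the peak at 275723 to 276270 (2.55-fold) had the rhoptry gene RhopH3 (PF3D7_0905400) as its nearest gene, 1159 bp from the summit. That at 744908 to 745331 (2.53-fold) had GAP50 (PF3D7_0918000), a motor anchor, at 1450 bp. IMC1c (PF3D7_1003600), of the inner membrane complex, was the nearest gene, at 1185 bp, of a peak of 2.44-fold. GLURP (PF3D7_1035300) and MSP3 (PF3D7_1035400) shared a peak of 2.24-fold. A peak of 2.205-fold lay between PF3D7_0217400, 791 bp from the summit, and the kinase gene CDPK1 (PF3D7_0217500), 1365 bp from it. The rhoptry neck gene RON3 (PF3D7_1252100) was the nearer neighbour, at 929 bp, of a peak of 2.197-fold. A peak of 2.62-fold lay between the protease gene DPAP3 (PF3D7_0404700), at 458 bp, and PF3D7_0404800, at 429 bp. The calmodulin gene CaM (PF3D7_1434200) had a peak on each side (2.35-fold and 2.197-fold), of which the first lay nearer to PF3D7_1434100 (241 bp) than to CaM (372 bp). A further peak, on chromosome 10 from 25503 to 26427 (2.503-fold), lay between the chromosome end and the var gene PF3D7_1000100. The remaining peaks of the 20 lay between genes for which, apart from PTEX150, only locus tags are given here. They were PF3D7_0114100 and PF3D7_0114200 (2.59-fold), PF3D7_0508800 and PF3D7_0508900 (2.49-fold), PF3D7_1463900 and PF3D7_1464000 (2.31-fold), and PF3D7_0931500 and PF3D7_0931600 (2.24-fold). The last lay between PF3D7_1436200 and PTEX150 (PF3D7_1436300, 2.21-fold), an export component whose end lay 4606 bp from that summit.

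The first comparison asked where along genes the acetyltransferase was mapped. Summits lay mostly between genes. Of 3388 nuclear summits, 2321 (68.5%, exact binomial 95% interval 66.9% to 70.1%) were intergenic, against 39.4% under random placement. Protein-coding genes held 1039 summits (30.7%, interval 29.1% to 32.3%), against 59.1% under random placement, where 95% of placements gave 57.4% to 60.7%. Pseudogenes held 12 summits, against 37.2 at random. Each of these 3 differences had a permutation p of 0.0001, the smallest that 10000 placements can give. RNA genes held 16 summits against 14.6 at random (permutation p = 0.703). The gene table used gives no strand and no exons, so promoters, terminators and introns were not told apart. Many of its spans hold no untranslated regions, so summits counted as between genes may lie in such regions.

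The location changed with the strength of the peak. Among peaks with a q above 0.05, 43.4% of summits lay in protein-coding genes (exact binomial 95% interval 40.4% to 46.4%). The share was 23.6% (20.4% to 27.1%) at a −log10 q of 2 to 3, and 5.75% (1.89% to 12.9%), 5 of 87 peaks, at a −log10 q of 10 or more. Peaks above the median fold had 20.7% of summits in protein-coding genes and the others 40.7%, a difference of 20.01 percentage points (permutation p = 1e-05, the smallest that 100000 resamples can give).

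**Figure D1:**
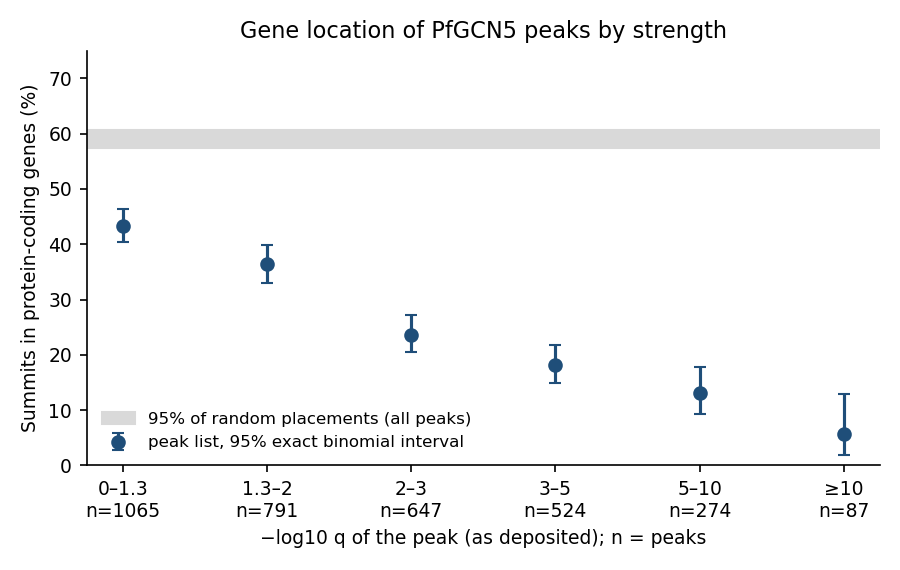
Percentage of summits inside protein-coding genes (y axis) for peaks grouped by their deposited −log10 q (x axis, with the number of peaks); points are shares with exact binomial 95% intervals and the grey band is the middle 95% of random placements of all nuclear peaks. The share went from 43.4% in the weakest group to 5.75% in the strongest, and all groups lay below the band.

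Summits gathered at some distance from gene ends. Between 500 and 1000 bp outside the nearest end of a protein-coding gene there were 724 summits, 2.18 times the 332 given by random placement. The ratio was 1.28 within 250 bp of a gene end, 1.87 at 250 to 500 bp and 2.001 at 1000 to 2000 bp. Beyond 2000 bp outside any protein-coding gene the number was 158, against 168.6 at random (adjusted permutation p = 0.455). Inside genes the ratio was 0.785 within 250 bp of an end, and from 0.429 to 0.488 deeper in the gene. Apart from the class beyond 2000 bp outside, each distance class had an adjusted permutation p of 0.0001. The placement here did not keep each summit inside or outside genes, so these ratios also carry the excess of summits between genes. The 158 summits beyond 2000 bp (ratio 0.937) therefore do not show that summits outside genes were as frequent there as at random. In all, 1752 summits (51.7%) lay outside and within 1000 bp of a protein-coding gene, against 29.5% at random. With a window of 1000 bp at each end, 2633 of 5282 protein-coding genes had a summit, against 2438 at random (95% of placements, 2383 to 2492; permutation p = 0.0001). This excess depended on the window and on the peaks used. The direction turned in the gene span alone (801 genes against 1463.5 at random), with a window of 500 bp (1732 against 1987) and among peaks with a −log10 q of at least 5 (326 against 361, permutation p = 0.0008). For those stronger peaks the deficit was not called under a placement that kept each summit inside or outside genes (326 against 342, permutation p = 0.219).

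**Figure D2:**
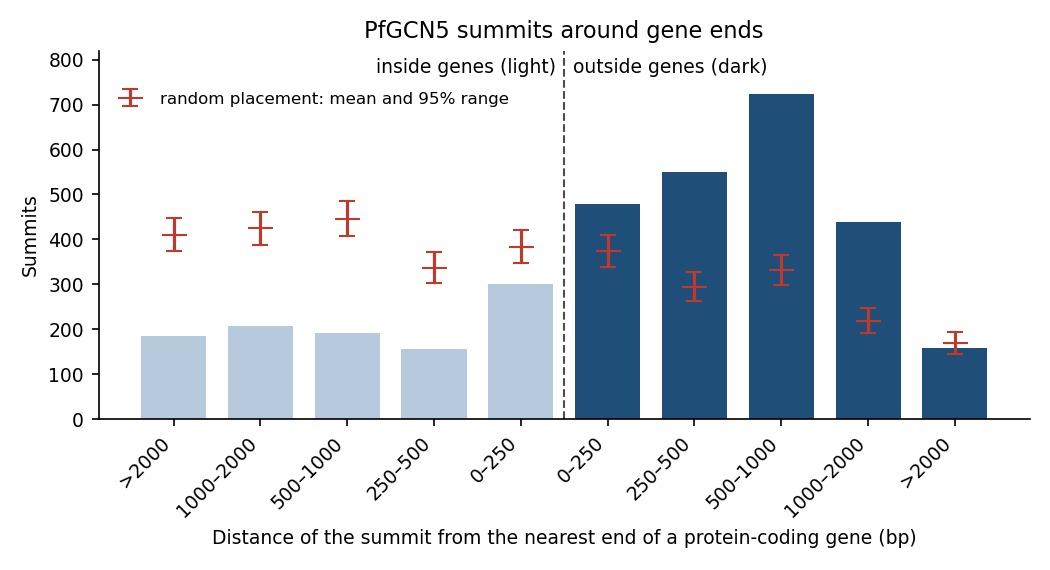
Number of summits (y axis) by distance in bp from the nearest end of a protein-coding gene (x axis), with light bars inside genes and dark bars outside; red marks give the mean and middle 95% of 10000 random placements. The tallest bar, 724 summits at 500 to 1000 bp outside, lies above its random range of 298 to 366.

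Gene lists were compared by the number of members with a summit in the gene or within 1000 bp of it. tRNA genes were more often near a summit than under random placement: 31 of 45 had one, against 11.9 at random (95% of placements, 5 to 19; adjusted permutation p = 0.0007). With each summit kept inside or outside genes the random number was 17.4, and the list was still called (adjusted permutation p = 0.0056). The highest folds at these tRNA genes had a median of 1.343, beside 1.338 over all peaks. The highest peak, of 1.79-fold, had its summit 1000 bp from PF3D7_0410100, at the edge of the window and nearer to PF3D7_0410000. It was followed by those near PF3D7_1103200 (1.49-fold), PF3D7_0702700 (1.48-fold) and PF3D7_0621600 (1.47-fold). Among peaks above the median fold the list was still called, with 16 members against 6.13 at random (adjusted permutation p = 0.012). At a −log10 q of at least 5, 1 tRNA gene was reached, against 1.29 at random, and the call ended. Numbers this small cannot show a direction. Inside the short tRNA spans themselves 2 genes had a summit, against 0.491 at random (adjusted permutation p = 0.126).

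The var genes, which encode the variable surface antigen PfEMP1, were less often near a summit. Of 61 members 22 had one, against 45.7 at random (95% of placements, 39 to 52; adjusted permutation p = 0.0007). The members with the highest peaks were PF3D7_0100100 (1.60-fold), PF3D7_0808600 and PF3D7_0900100 (both 1.44-fold) and PF3D7_0421300 (1.41-fold). With each summit kept inside or outside genes the random number was 39.6, and the list was still called (adjusted permutation p = 0.0014). With peaks of −log10 q of at least 5, 1 member was reached against 7.81 at random and the call ended (adjusted permutation p = 0.070). Whether reads could be placed uniquely in these similar genes was not analysed here.

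Genes of merozoite invasion had 20 of 27 members near a summit, against 13.9 at random, which missed the threshold after adjustment (permutation p = 0.031, adjusted p = 0.102). The call depended on the peaks and the window used. At a −log10 q of at least 5, 10 members had a summit against 2.26 at random (adjusted permutation p = 0.0014), and among peaks above the median fold 15 against 8.43 (adjusted permutation p = 0.034). With all peaks the list was also called with a window of 2000 bp (25 against 17.2, adjusted permutation p = 0.0145) and with any overlap of the interval (23 against 14.8, adjusted permutation p = 0.020), but with a window of 500 bp the number was 11 against 11.8. After MSP1 the highest members were MSP3 and GLURP, at their shared peak of 2.24-fold, and MSP2 (PF3D7_0206800), which shared a peak of 2.15-fold (chromosome 2, 274647 to 275658) with MSP5 (PF3D7_0206900.1). The other members with such a peak, named after their values were seen, were EBA175 (PF3D7_0731500, 1.76-fold), MSP6 (PF3D7_1035500, 1.72-fold), AMA1 (PF3D7_1133400, 1.59-fold), MSP7 (PF3D7_1335100, 1.53-fold) and RH2b (PF3D7_1335300, 1.46-fold).

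Regulators of transcription and chromatin had fewer members near a summit than random placement gave, without passing the threshold. ApiAP2 transcription factors had 12 of 28 against 17.5 (adjusted permutation p = 0.102), led by PF3D7_0404100 (1.65-fold), AP2-L (PF3D7_0730300, 1.54-fold), AP2-G2 (PF3D7_1408200, 1.45-fold) and PF3D7_1222400 (1.41-fold). Histone and chromatin genes had 11 of 29 against 15.4 (adjusted permutation p = 0.374), led by histone H3 (PF3D7_0610400, 1.78-fold), histone H2B (PF3D7_1105100, 1.72-fold), SET8 (PF3D7_0403900, 1.53-fold) and SET10 (PF3D7_1221000, 1.51-fold). With a window of 500 bp both lists passed the threshold as lower, with 6 ApiAP2 members against 15.9 (adjusted permutation p = 0.0005) and 6 chromatin members against 13.2 (adjusted permutation p = 0.020). Protein-coding genes as a whole were also below random with that window (1732 against 1987). With each summit kept inside or outside genes, run with the 1000 bp window only, neither list was called. ApiAP2 factors then had 12 against 16.2 and chromatin genes 11 against 15.3 (both adjusted permutation p = 0.352). The lower numbers may therefore follow from the location of summits outside genes. Among peaks with a −log10 q of at least 5 the direction turned for chromatin genes, without a call (3 against 2.52, or 2.16 with each summit kept inside or outside genes).

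Among metabolic and stress lists none passed the threshold. Glycolysis had 9 of 12 members with a summit against 5.06 at random (permutation p = 0.036, adjusted p = 0.102), with GPI (PF3D7_1436000, 1.51-fold), PGM1 (PF3D7_1120100, 1.43-fold), GAPDH (PF3D7_1462800, 1.38-fold) and aldolase (PF3D7_1444800, 1.38-fold) highest. Heat shock proteins and chaperones had 10 of 16 against 7.55 (adjusted permutation p = 0.595). Their highest members were HOP (PF3D7_1434300, 2.097-fold), HSP90 (PF3D7_0708400, 1.68-fold), an HSP40 gene (PF3D7_0501100.1, 1.53-fold) and ClpB1 (PF3D7_0816600, 1.51-fold). Antioxidant genes had 4 of 13 against 4.96 (adjusted permutation p = 0.853): TPx2 (PF3D7_1215000, 1.43-fold), TrxR (PF3D7_0923800.1, 1.41-fold), GluPho (PF3D7_1453800, 1.38-fold) and AOP (PF3D7_0729200, 1.35-fold). Haemoglobin digestion had 6 of 10 against 4.13 (adjusted permutation p = 0.513), led by PMI (PF3D7_1407900, 1.39-fold), FP1 (PF3D7_1458000, 1.36-fold), FLN (PF3D7_1360800, 1.35-fold) and FP3 (PF3D7_1115400, 1.34-fold).

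Protein kinases, exported proteins, gametocyte genes and rRNA genes stayed within their random ranges. Protein kinases had 9 of 15 members with a summit against 7.81 (adjusted permutation p = 0.853), led by PKAc (PF3D7_0934800, 1.82-fold), CDPK3 (PF3D7_0310100, 1.52-fold), PKG (PF3D7_1436600, 1.5003-fold) and eIK2 (PF3D7_0107600, 1.41-fold). Exported proteins had 8 of 17 against 8.31 (adjusted permutation p = 1), led by SBP1 (PF3D7_0501300, 1.59-fold), MAHRP1 (PF3D7_1370300, 1.49-fold), REX2 (PF3D7_0936000, 1.42-fold) and MESA (PF3D7_0500800, 1.41-fold). Gametocyte genes had 5 of 13 against 6.67 (adjusted permutation p = 0.513), led by HAP2 (PF3D7_1014200, 1.65-fold), Pfs25 (PF3D7_1031000, 1.54-fold), Pf11-1 (PF3D7_1038400, 1.32-fold) and CCp1 (PF3D7_1475500, 1.31-fold). The Pfs25 peak lay in a stretch of chromosome 10 where the caller's background was raised. rRNA genes had 6 of 28 against 10.9 (adjusted permutation p = 0.491), with PF3D7_1418700 (1.44-fold), PF3D7_0830000 (1.37-fold), PF3D7_1418500 (1.31-fold) and PF3D7_0531600 (1.30-fold) highest.

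**Figure D3:**
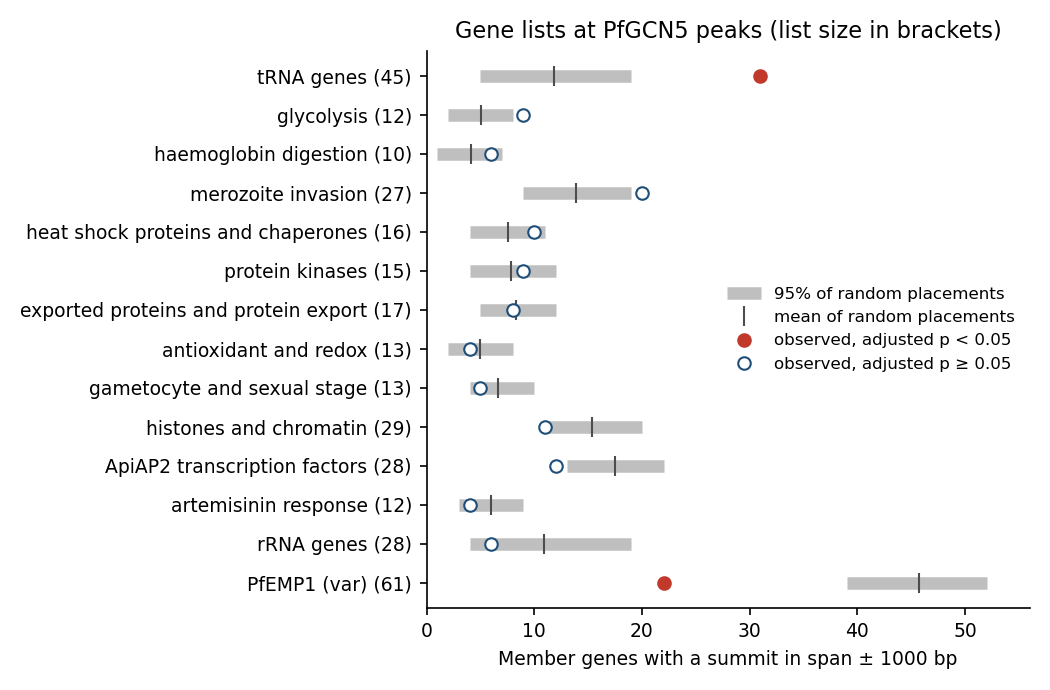
Number of member genes with a summit in the gene or within 1000 bp of it (x axis) for 14 gene lists (y axis, list size in brackets); circles are observed, filled where the adjusted permutation p was under 0.05, and grey bars are the middle 95% of random placements with their mean. tRNA genes, with 31 members against 11.9 at random, lie above their bar and var genes, with 22 against 45.7, below.

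Of 12 genes studied for the response to artemisinin, 4 had a summit nearby, against 6.01 at random (adjusted permutation p = 0.513). PI3K (PF3D7_0515300), a lipid kinase, had a peak with its summit outside its span. That peak, on chromosome 5 from 635894 to 636392, had a fold of 1.94 (95% Poisson interval 1.70 to 2.204). The ferredoxin gene FD (PF3D7_1318100) had 2 summits, the higher at 1.70-fold (1.48 to 1.95). K13 (PF3D7_1343700), the Kelch protein whose mutations mark artemisinin resistance, had a peak with its summit outside its span. That peak had a fold of 1.36 (1.16 to 1.58) and ranked 1407 among the nuclear peaks. The falcipain gene FP2a (PF3D7_1115700) had a peak with its summit in its span, of 1.28-fold (1.08 to 1.49). The q of that peak was above 0.05 (−log10 q of 1.14). With peaks at a q at or under 0.05, 3 members had a summit, against 4.56 at random (adjusted permutation p = 0.766). No summit was listed at the transporter genes MDR1 (PF3D7_0523000) and CRT (PF3D7_0709000), at ARPS10 (PF3D7_1460900.1), CORO (PF3D7_1251200), UBP1 (PF3D7_0104300), AP2-MU (PF3D7_1218300) and ATG18 (PF3D7_1012900), or at the chaperone gene BiP (PF3D7_0917900). The gene of PfGCN5 itself (PF3D7_0823300) also had no summit in its span or within 1000 bp.

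Some genes carried several summits. In the span and 1000 bp at each end, 47 genes had 4 or more. This number was not compared with random placement, and longer spans leave room for more summits. PF3D7_1324300 had 9, PF3D7_0718000 had 7 and PF3D7_1021700 had 6. With 5 each followed PF3D7_0208300, PF3D7_0417400, PF3D7_0511500, PF3D7_0724000, PF3D7_0724700, PF3D7_0809600 and PF3D7_1023100. The highest fold at these 10 genes was 1.61, at PF3D7_0208300.

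Along the chromosomes the peaks were spread nearly in proportion to length. No chromosome passed the threshold after adjustment. Chromosome 10 had the highest density, 279 peaks against 243 by length (permutation p = 0.018, adjusted p = 0.253), and chromosome 1 the lowest, 74 against 90.3 (adjusted permutation p = 0.684). Among peaks with a −log10 q of at least 5, chromosome 10 had 47 against 25.9 and passed the threshold. Of those 47 peaks, 12 lay in a stretch from 1177656 to 1254503 in which the background of the caller at 38 neighbouring peaks was 1.52 to 2.01 times the most frequent one. Without the peaks of that stretch no chromosome passed the threshold. The stretch was picked from these data for its background, and the chromosome length was left unchanged. Since most of the 47 peaks lay outside it, the lost call does not show that the stretch accounted for the excess. The 100 kb next to the chromosome ends, which hold many of the var genes but not the 24 members in the core, had 354 summits (10.4%, exact binomial 95% interval 9.44% to 11.5%), against 12.02% under random placement (permutation p = 0.0033). With a circular shift of the peaks along each chromosome the deficit was of similar size but not called (10.4% against 12.05%, permutation p = 0.054). The call also ended among peaks with a −log10 q of at least 5 (11.6% against 12.1%, permutation p = 0.807). Under a placement that kept each summit inside or outside genes the share was lower than random both for all peaks (10.4% against 15.2%, permutation p = 0.0001) and for the stronger peaks (11.6% against 17.4%, permutation p = 0.0038).

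**Figure D4:**
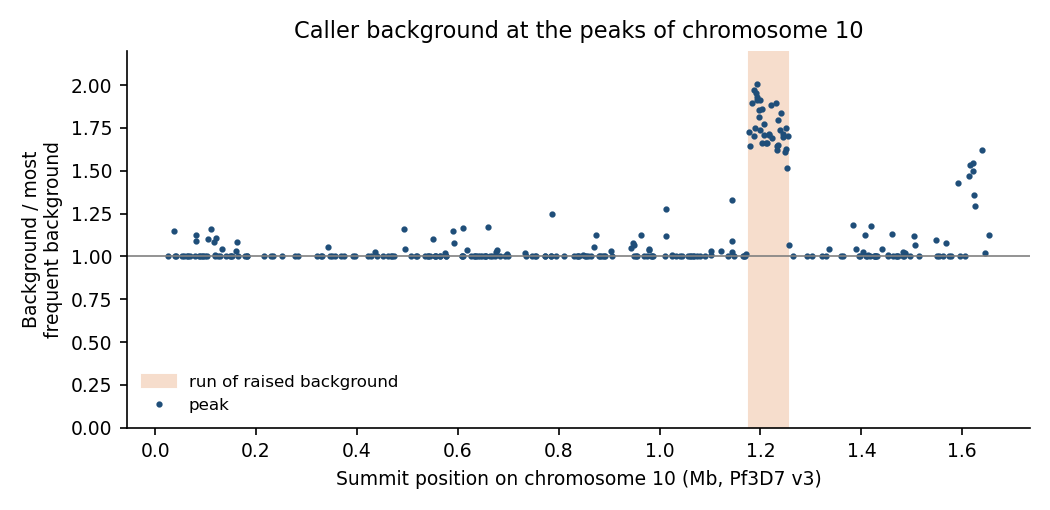
Background of the peak caller at each peak of chromosome 10, divided by the most frequent background in the list (y axis), against the summit position in Mb (x axis); each point is 1 peak and the shaded band spans 38 neighbouring peaks. In the band, picked as the longest run at 1.5 or more, the values lie between 1.52 and 2.01. The nearest peaks on either side lie at 1.01 and 1.06, and the 10 peaks on each side reach 1.33 before and 1.18 after.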

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

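All tests in this part were chosen after the results were seen. For the count of invasion genes by cluster, the expected outcomes were written down before that count was made.

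The apicoplast genome was outside all comparisons, yet it held 8 peaks. Its highest peak had a fold of 1.79 (95% Poisson interval 1.67 to 1.92), and the lowest 1.16. The background of the caller at these peaks was 3.84 to 4.77 times the most frequent one. No cause was tested.

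Summits lay outside protein-coding genes, more so the stronger the peak. Shifted coordinates are argued against, since the share in genes was lowest within 250 bp of no shift on 14 of 14 chromosomes. Taken as a whole, peaks with a q above 0.05 did not lie as random positions would. Of these, 43.4% lay in genes, against a mean of 59.0% in 10000 random placements of these peaks. The 2.5th percentile of the placements was 56.1% (permutation p = 0.0001, the smallest they can give). The comparison cannot tell whether part of them are random positions, nor whether a larger such part among weaker peaks gave the change with strength. A higher input over genes, which could remove peaks there, cannot be told apart: 17.5% of summits in genes and 26.8% of the others had a background above the most frequent one, but the background is known only where a peak was called. Open chromatin and serum binding without PfGCN5 were not tested, since a pre-immune library was not analysed here, and no biological explanation was tested.

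Invasion genes carried strong peaks. Location outside genes does not account for the excess, since members with a summit at a −log10 q of at least 5 were 5.02 times those of a placement that kept each summit inside or outside genes (adjusted permutation p = 0.0014). Nor do neighbouring members that share peaks: counted once per cluster of members within 10 kb, 6 of 19 clusters had a strong summit, against 1.82 at random (permutation p = 0.0057). The 10 members rested on 8 peaks, and the p by cluster was not adjusted for the choice of this list. GC content and mappability stayed untested, and no biological explanation was tested.

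The background of the caller was raised along a stretch of chromosome 10. The stretch was picked as the longest run of neighbouring peaks at 1.5 times the most frequent background or more, so its lower bound follows from that rule. From 1177656 to 1254503 (76.8 kb), 38 peaks had a background 1.52 to 2.01 times the most frequent one, with a median of 1.73. The nearest peaks before and after, 7047 and 2493 bp away, were at 1.01 and 1.06. Among the 10 peaks on each side the highest were 1.33 before and 1.18 after. An extra copy of the stretch in the parasites used is a candidate explanation, but it cannot be told apart from other regional causes, since the stretch was picked for its background and input coverage and repeats were not analysed here. The stretch held 49.4 peaks per 100 kb, against 14.7 over the nuclear genome, so its peaks, Pfs25 included, may partly follow from it.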

How the results depend on the processing

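The added alternatives (a q at or under 0.05, gene spans alone, placement within class, and leaving out the chromosome 10 stretch) were chosen after seeing the data, as were all alternatives for the share just outside genes and for coding genes with a summit, which replaced the 5′ flanks. No paired analysis was possible because the series has 1 ChIP library and 1 list. Of 217 recomputed values with a test, merging left out, 168 kept direction and side of the threshold. The share of summits in protein-coding genes stayed lower in all 7 alternatives run, merging included (0.193 to 0.535 times random), and the share just outside genes stayed higher in all 9 (1.54 to 2.09 times). GC-matched placement, unique 50-mers, orientation, 5′ flanks and GC content were not run, and merging changed nothing because no intervals overlapped. Depth limits single folds: the Poisson interval had a median half-width of 0.209. Apart from changes due to fewer peaks or smaller windows by construction, the cause was not tested.

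With a −log10 q of at least 5 the list fell to 365 peaks, 1 chromosome passed and 1 list was called instead of 2. The subtelomeric share was 11.6% and no longer called (also at 10.4% with a circular shift), but was called as lower with placement within class (11.6% against 17.4%). Coding genes with a summit turned to 326, below 361 at random. Invasion genes were called (10 members). The var list was no longer called (1). Directions turned, without a call, for tRNA genes (1 against 1.29), chromatin (3 against 2.52), glycolysis (0 against 0.703), gametocyte (2 against 1.47), kinases (1 against 1.19), haemoglobin digestion (0 against 0.558) and artemisinin genes (2 against 0.962). At random numbers this small, such a turn does not show a direction. With placement within class as well, values were the same counts against other random means: coding genes 326 against 342 (not called), invasion 10 (1.99, called), chromatin 3 (2.16), glycolysis 0 (0.854), gametocyte 2 (1.23), kinases 1 (1.02), haemoglobin digestion 0 (0.790), var 1 (4.64, not called), tRNA 1 (2.67), artemisinin 2 (0.945), with 1 list called.

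Among peaks above the median fold invasion genes were called (15), while antioxidant (4 against 2.86) and exported genes (7 against 4.92) turned. In the core exported genes turned (6 against 5.61), as with any overlap (9 against 8.93), where invasion genes were called (23). With 500 bp windows 4 lists were called, with ApiAP2 (6) and chromatin (6) now lower. Coding genes (1732 against 1987), invasion (11 against 11.8), chaperones (5 against 6.20) and haemoglobin digestion (2 against 3.18) turned. With 2000 bp windows 4 lists were called, with invasion (25) and ApiAP2 (14) added, and gametocyte genes turned (9 against 8.29).

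With a q at or under 0.05 ApiAP2 factors were called as lower (7), and antioxidant (4 against 3.71) and exported genes (7 against 6.22) turned. In gene spans alone ApiAP2 (3) and chromatin genes (0) were called as lower and tRNA genes lost the call (2). Coding genes (801), invasion (6 against 9.37), chaperones (1 against 4.63), glycolysis (0 against 2.63), kinases (1 against 5.38) and haemoglobin digestion (1 against 2.08) turned.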

Other observations

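The tests in this part were chosen after the results were seen. Long stretches without a summit were more frequent than under random placement. There were 7 of at least 50 kb, against a mean of 2.01 in 1000 random placements (one-sided permutation p = 0.005). The longest was the first 127.5 kb of chromosome 2. On chromosome 7 no summit lay between 498517 and 575513, an interval that holds 5 var genes, and on chromosome 4 none between 555108 and 605509, which holds 3. A stretch on chromosome 12 from 27985 to 87662 held 2 var genes. In all, 11 var genes lay in 4 of these stretches. The stretches on chromosome 14 from 175268 to 227418 and on chromosome 7 from 1175458 to 1238458 and from 181807 to 232654 held none. The 11 var genes were not compared with a random number, and they are not a result apart from the lower count of the var list. Input coverage and unique placement of reads in these stretches were not analysed here.

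The gene of GTP cyclohydrolase, GCH1 (PF3D7_1224000), the entry enzyme of folate synthesis, was named after its values were seen, for the background of the caller. Its 2 peaks, on chromosome 12 from 974350 to 975536, had backgrounds of 4.70 and 4.74 times the most frequent one, at folds of 1.24 and 1.07. Among all nuclear peaks, 92.4% were below 1.1 times that background.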
